A study of Mus musculus with 2 samples.

How the data were processed

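Poly(A) RNA longer than 200 bases from brown adipose tissue of the male B6NCrl mouse at 24 weeks was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 with 1 technical replicate each. Both carry the same donor identifier in the labels, which describe the material as coming from an individual mouse, so whether they came from separate animals is not settled. For each library the authors deposited a table of genes and a table of transcripts, made for that library alone. Per the deposited description, reads were quantified from alignments to the transcriptome of mouse genome mm10 with GENCODE M4 annotation; the aligner, the quantifier and the read length are not given in the sources used here.

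The deposited expected counts are the authors' estimates of reads per gene or transcript; they are not scaled and need not be whole numbers. The deposited TPM values were scaled by the authors for effective length and to the same total in each library, spike-ins included. The deposited FPKM values were scaled by the authors per kilobase and by the number of reads, and were used only as an alternative unit for the correlation between libraries. The deposited posterior mean TPM values come from the authors' model and are above 0 even for genes with no read; the deposited interval bounds of the posterior TPM carry no stated level. The deposited isoform percentages, the percent of a gene's TPM held by a transcript, were not used, and shares were computed again from transcript TPM. The effective length was 29 bases below the length for most transcripts, per the deposited values.

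Identifiers (Ensembl) were matched without their version to GENCODE M21 on the same genome build for symbols, coordinates and gene types: 42462 of 43346 genes matched, 21474 of them protein-coding. Genes without a match took 0.528% and 1.55% of gene counts in replicates 1 and 2. All 419 members of the lists were found. Entries that name no gene were left out of library sizes, shares and tests. They were 97 spike-in sequences, with 2.44% and 2.36% of expected counts, and 26248 entries with numeric identifiers that nothing in the files explains, with 0.00530% and 0.00558%. The total was 1.18e+07 expected counts in replicate 1 and 1.21e+07 in replicate 2. A gene with no count may have a share of up to 2.54e-05% in replicate 1 and 2.48e-05% in replicate 2, the limit that 3 counts set. Intervals of shares are exact (Clopper-Pearson) at 95%; intervals and limits cover counting error only.

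The lists, families, isoform genes, quantities and alternatives were chosen before the data were examined, except for those named here as later. With 1 group there is no contrast between conditions. Levels are mean and SD of TPM over n = 2 libraries, and a gene was called detected at a TPM of at least 1 in both. Shares of TPM were computed over genes without spike-ins. The level of each of 39 gene lists is the median over its members of mean TPM, set beside the medians of 10000 random lists of the same size drawn from protein-coding genes. For each of 30 gene families the log2 ratio of TPM + 0.1 of the most abundant to the next member was taken in each library; a family was counted when the order was the same in both libraries and the mean ratio exceeded the difference between them. For 26 genes with at least 20 counts in each library the share of each transcript in the TPM of its gene was taken.

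Differences between the libraries are log2(CPM + 0.5) of replicate 2 minus replicate 1, where CPM are expected counts scaled by library size and by TMM factors (0.970 and 1.03) from edgeR 4.0.16 in R 4.3.3. Genes with a summed expected count of at least 100 were used, and a 2-fold difference was the threshold for counts of genes. No test between the libraries was run, because there is 1 library on each side. For 29 lists with at least 3 tested members the median difference was set beside 10000 random lists matched on mean expression in 20 bins; the middle 95% of these is the range of random lists. The other 10 lists had fewer members with enough counts. The correlation between libraries used log2(TPM + 1) over genes with a mean TPM of at least 1. The biological coefficient of variation is the square root of the common dispersion from edgeR on rounded expected counts with an intercept alone and the filter filterByExpr; DESeq2 1.42.0 gave an alternative. The chi-square of rounded counts against Poisson sampling covered genes with a summed count of at least 10.

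To find reads that near-identical sequences share, the transcripts of each named gene in GENCODE M21 were split into 30-base windows, and the percent of windows found in transcripts of other genes, on either strand, was recorded. The window length was set from the difference between length and effective length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

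Genes named are the 20 nuclear protein-coding genes with the highest mean TPM, the 4 most abundant members of each list, every member of the thermogenic and white adipocyte lists, every family member, every isoform gene, and in each direction the 10 protein-coding genes with the largest difference among those with a summed count of at least 500. Genes named outside this rule are said to be so in the text.

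The steps were tested on simulated data with the measured means and depths. With no gene changed, a coefficient of variation of 0.1, 0.25 or 0.4 was recovered as 0.0985, 0.247 or 0.388. With 200 genes changed it was recovered as 0.177, 0.281 or 0.405, so changed genes raised the estimate. At 0.25, with 200 genes changed, a 2-fold difference was exceeded by 50% of genes changed 2-fold, 86% of those changed 3-fold, all of those changed 4-fold or 8-fold, and 6.01% of unchanged genes. Of 20 lists of 10 genes, 15% lay above the range of random lists when changed 1.2-fold, 90% when changed 1.5-fold and 100% when changed 2-fold, while 3.5% to 5% of 200 unchanged lists lay outside it. Genes were simulated independently of each other, so these shares do not carry over to lists whose members vary together.

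Alternatives were another TPM minimum, expected counts or posterior mean TPM in place of TPM, totals without mitochondrial genes, another pseudocount or filter, DESeq2 size factors, CPM without TMM, the ratio of TPM, and each library alone. Totals with the nuclear copies of mitochondrial genes, counts of protein-coding genes alone and plain CPM for list differences were added after the data had been seen. Sequence reads and alignments are not among the files, so strain variants and coverage along genes were left out.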

Results

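Brown adipose tissue is the fat depot that burns fuel to make heat in its many mitochondria. Poly(A) RNA from this tissue of the adult male B6NCrl mouse at 24 weeks was sequenced in 2 libraries, which form 1 group and are numbered in the labels as biological replicates 1 and 2. The labels also give both the same donor identifier and describe the material as coming from an individual mouse; they do not settle whether separate animals were used, so the spread between them is not known to be a spread between animals. The design holds no treatment, genotype or other tissue; the questions it can answer are which genes the tissue transcribed, at what level, and how far the 2 libraries differed. The deposited tables held 1.18e+07 expected counts in replicate 1 and 1.21e+07 in replicate 2. Annotated genes took 1.15e+07 and 1.18e+07 of these, and nuclear protein-coding genes 4.39e+06 and 4.98e+06. Levels are in TPM (transcripts scaled to a fixed total per library), as mean ± SD over n = 2 libraries, and coordinates are mm10 gene spans. An exact permutation test over 2 libraries cannot give a p below 0.5, so no p-value was computed.

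Transcripts of mitochondria and of fat metabolism were prominent. The 13 protein genes and 2 rRNAs of the mitochondrial genome held 57.4% ± 1.98 (SD, n = 2) of the TPM of all genes, and nuclear protein-coding genes held 23.6% ± 2.13. Among nuclear protein-coding genes the highest levels belonged to Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids (4934 ± 3670 TPM), and to Fabp4, the fatty acid carrier of adipocytes (4799 ± 329 TPM). Scd1 lies on chromosome 19 (44394455 to 44407879, minus strand) and Fabp4 on chromosome 3 (10204088 to 10208576, minus strand). The spread of Scd1 came from a level of 2339 TPM in replicate 1 against 7529 in replicate 2, whereas Fabp4 stood at 4567 and 5032. The 20 most abundant nuclear protein-coding genes also included Dbi, an acyl-CoA binding protein (2124 ± 200 TPM), Cox8b, a subunit of cytochrome c oxidase (1961 ± 198), and Atp5b, the catalytic subunit of ATP synthase (1712 ± 94.0). Aldoa of glycolysis (1625 ± 160), Car3, a carbonic anhydrase of fat and muscle (1514 ± 27.9), and Thrsp, a lipogenic protein (1481 ± 115), were among them too. The 10 most abundant nuclear protein-coding genes together held 2.38% ± 0.482 of TPM. TPM of at least 1 in both libraries was reached by 9690 genes, 8846 of them protein-coding, and TPM of at least 100 by 348 protein-coding genes.

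Heat production by brown fat rests on Ucp1, which lets protons back into the mitochondrial matrix without making ATP. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452, plus strand) ranked 13 among nuclear protein-coding genes, with 1300 TPM in replicate 1 and 1487 in replicate 2 (1394 ± 132). Of 16 thermogenic genes, 14 reached a TPM of 1 in both libraries and 5 reached 100, and the median member stood at 35.0 TPM. Besides Ucp1 and Cox8b, the 5 were Cox7a1, another cytochrome c oxidase subunit (881 ± 183 TPM), Cidea, a lipid droplet protein (837 ± 1.24), and Letmd1, a mitochondrial membrane protein (130 ± 4.04). The proton channel gene Otop1 (34.4 ± 7.95 TPM), the lipid droplet gene Plin5 (35.6 ± 7.92), the potassium channel gene Kcnk3 (28.7 ± 0.205), Nrg4 (47.1 ± 8.50) and Pank1 (44.2 ± 6.63) were at intermediate levels. Low levels were found for Mpzl2 (10.7 ± 3.92 TPM), for Dio2, the deiodinase that activates thyroid hormone (4.89 ± 2.88), and for Ppargc1a, the coactivator of mitochondrial genes (4.75 ± 2.62). Elovl3, a fatty acid elongase, differed most between the libraries, with 8 TPM in replicate 1 and 40.7 in replicate 2. The secreted factors Fgf21 and Bmp8b stayed below 1 TPM, with 3 and 2 counts of Fgf21 in replicates 1 and 2.

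Every member of the nuclear lists for the respiratory chain was transcribed in both libraries. The median member stood at 1116 TPM for 11 genes of complex IV, at 655 for 8 genes of complex III, at 379 for 13 genes of ATP synthase and at 270 for 11 genes of complex I. Each of these medians lay above those of all 10000 random lists of protein-coding genes of the same size. The random lists drew on all protein-coding genes, and only 8846 of the 21474 matched ones reached 1 TPM in both libraries. Lists of heat shock, erythroid and fast skeletal muscle genes had the same rank, so it does not set the respiratory chain apart. Leading members were, after Cox8b, Cox7b of complex IV (1870 ± 9.44 TPM), Uqcrh of complex III (1105 ± 181) and Ndufa4, listed with complex I (1574 ± 389). The 17 genes of the tricarboxylic acid cycle had a median of 385 TPM, led by the aconitase gene Aco2 (911 ± 19.5), and 16 of them reached 100 TPM in both libraries. The 13 mitochondrially encoded protein genes had a median of 30703 TPM, with mt-Atp6 (97619 ± 2513; chromosome M, 7927 to 8607), mt-Co2 (69147 ± 7757) and mt-Co1 (66460 ± 11749) highest. These values are uncertain, because the nuclear genome carries 7 annotated copies of mitochondrial sequence on chromosome 1 and 99.5% of the 30-base windows of mt-Atp6 also occur in transcripts of other genes.

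Genes that burn and genes that store fat were both at high levels. The 20 genes of fatty acid oxidation had a median of 303 TPM and 14 of them reached 100 in both libraries, led by Hadhb (939 ± 96.8), Ech1 (839 ± 11.01), Acaa2 (710 ± 80.3) and Acadm (575 ± 41.3). All 19 genes of fatty acid and triglyceride synthesis reached 1 TPM, with a median of 108 that rested on 67.1 in replicate 1 and 152 in replicate 2. The leading members after Scd1 and Thrsp were Fasn, the fatty acid synthase (1373 ± 57.4), and Acly, which makes cytosolic acetyl-CoA (765 ± 173). Lipolysis and fatty acid uptake, 18 genes with a median of 137 TPM, was led after Fabp4 by Pnpla2, the triglyceride lipase (744 ± 196), Fabp3 (351 ± 116) and Lpl, the lipoprotein lipase (315 ± 131). Glucose uptake and glycolysis had a median of 177 TPM over 22 genes, led after Aldoa by Gpd1 (1324 ± 118), Eno1 (1037 ± 31.7) and Ldha (495 ± 0.898). The 12 general adipocyte genes had a median of 308 TPM, and they included the hormone gene Adipoq (430.5 ± 41.9) and Cfd, which encodes adipsin (531 ± 365, from 789 in replicate 1 and 273 in replicate 2).

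The 23 brown adipocyte transcription factors had a median of 3.57 TPM, and 17 of them reached 1 TPM in both libraries. Cebpa (87.9 ± 6.76 TPM), Pparg, the receptor that drives fat cell identity (68.6 ± 20.7), Cebpb (52.6 ± 3.19) and Esrra, a regulator of mitochondrial genes (26.9 ± 1.10), were highest. Prdm16 (2.45 TPM in replicate 1 and 3.89 in replicate 2) and Ebf2 (5.83 and 11.5) were lower. Zic1, Lhx8 and Tbx15, named after their values were seen, stayed below 1 TPM in both libraries. Of 17 adrenergic receptors and signalling genes, 11 reached 1 TPM. They were led by Gnas, the stimulatory G protein subunit (878 ± 176), by Prkar2b (215 ± 44.1) and Prkaca (69.5 ± 15.03), subunits of protein kinase A, and by Adrb3 (46.3 ± 21.9), the receptor through which noradrenaline drives heat production. Of 17 secreted factors, 10 reached 1 TPM, with Angptl4 (70.1 ± 14.5) and Vegfa (51.7 ± 5.47) highest. Creatine cycling genes had a median of 4.04 TPM (3.89 in replicate 1 and 2.47 in replicate 2), above 92.9% of random lists, and calcium cycling genes 0.860, above 62.3%.

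In each of 30 gene families the most abundant member was the same in both libraries, and in 29 of them its lead over the next member exceeded the difference between the libraries. Ucp1 exceeded Ucp3 by 6.08 ± 0.64 on the log2 scale, and the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 6.59 ± 0.30. Cpt1b, the muscle form of the enzyme that admits fatty acids to mitochondria, exceeded Cpt1a by 6.22 ± 0.42, although 79.8% of its windows occur in transcripts of other genes and its count is uncertain. Scd1 exceeded Scd2 by 6.22 ± 1.15, Adrb3 exceeded Adrb1 by 3.07 ± 0.94 and Cox8b exceeded Cox8a by 0.96 ± 0.04. Dio2 led its family, but Dio1 had no count in replicate 1 and 1 in replicate 2, so the size of that lead is not known. The exception was Pparg over Ppara, with a lead of 2.80 in replicate 1 and 0.90 in replicate 2. By expected counts, which are not divided by transcript length, Cox7a1 was below Cox7a2 (mean log2 ratio -0.32, against 0.79 by TPM) and Slc27a2 below Slc27a1 (-0.11, against 0.35).

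**Figure D1:**
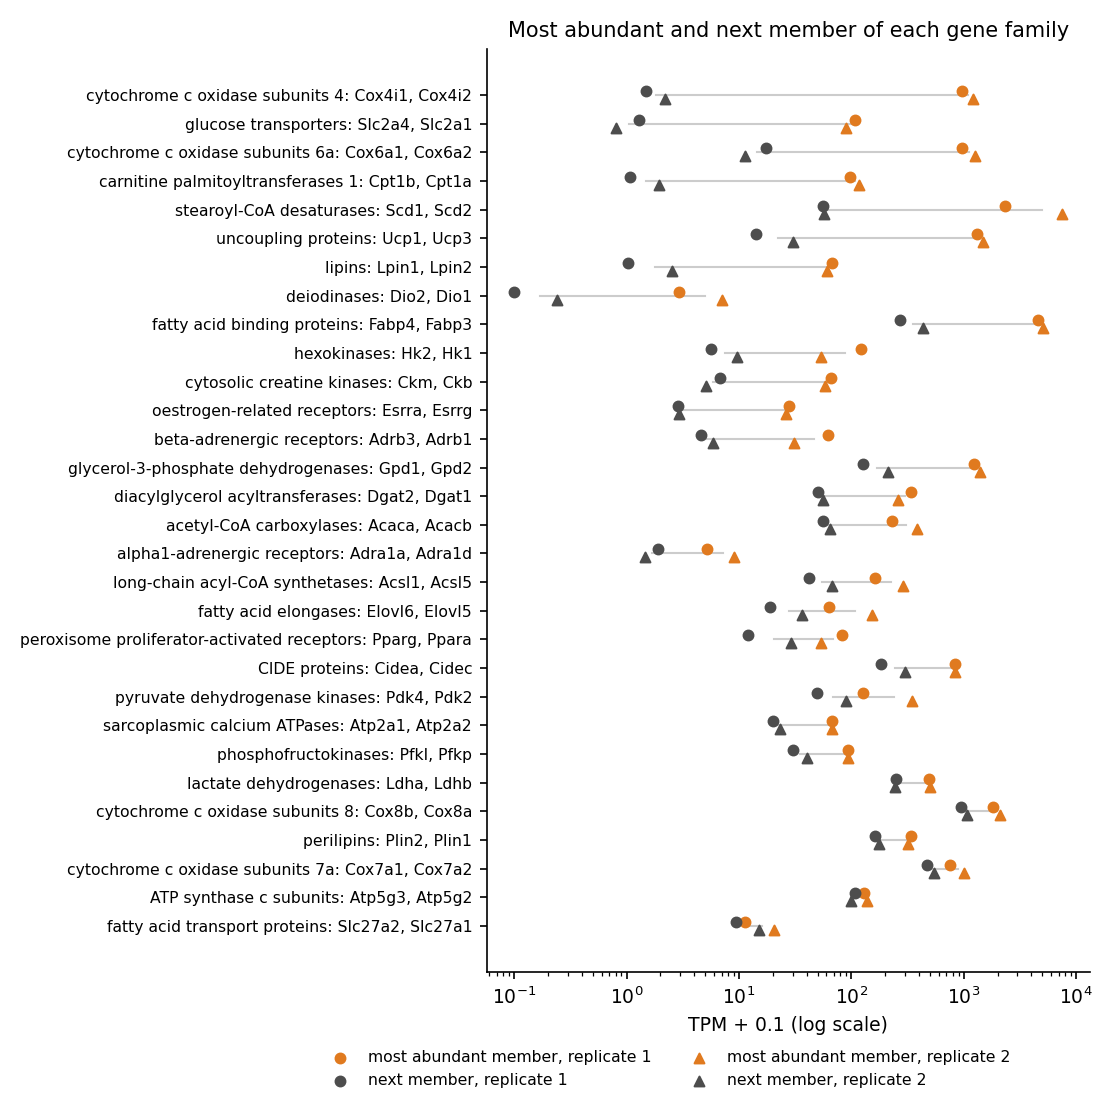
TPM + 0.1 on a log axis for the most abundant member (orange) and the next member (grey) of 30 gene families, 1 symbol per library (circles for replicate 1, triangles for replicate 2), with a grey line joining the means. Ucp1 stands at 1300 and 1487 TPM against 14.0 and 30 for Ucp3; the order of Cox7a1 and Cox7a2 and of Slc27a2 and Slc27a1 turns round when expected counts are used.

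Genes listed as markers of white fat, muscle, blood and vessels were also present, with medians below those of the nuclear respiratory chain lists. Among 12 white adipocyte genes with a median of 3.02 TPM, 8 reached 1 TPM in both libraries. These were Retn, the resistin gene (54.9 ± 5.35), Nnat (41.7 ± 11.9), Sncg (37.7 ± 11.02), the leptin gene Lep (28.0 ± 12.1), Npr3 (12.8 ± 0.290), Slc7a10 (3.22 ± 0.870), Wfdc21 (2.82 ± 2.29) and Hoxc8 (2.24 ± 0.0566). Mest (1.11 ± 0.764 TPM) and Agt (0.630 ± 0.0849) did not reach it in both, Hoxc9 had 1 count in replicate 2, and Hoxc10 had none. Only Slc27a1 of 7 beige adipocyte genes reached 1 TPM (12.2 ± 3.95). All 14 fast skeletal muscle genes did, with a median of 58.3 TPM and Tnnt3 (148 ± 4.03), Acta1 (107 ± 3.27) and Mylpf (96.7 ± 11.3) at the top. This list shares Atp2a1 with the calcium cycling list and Ckm with the creatine kinase family. The median was 14.2 TPM for fibroblast and progenitor genes, led by Dcn (109 ± 21.2). It was 7.59 for endothelial genes (8.295 in replicate 1 and 4.77 in replicate 2), led by Egfl7 (21.4 ± 1.98), 4.91 for slow skeletal and heart muscle genes, 3.91 for smooth muscle and pericyte genes, and 3.35 for macrophage genes, led by Lyz2 (45.5 ± 10.5). The 7 erythroid genes had a median of 56.9 TPM (90.2 in replicate 1 and 23.6 in replicate 2), with Hbb-bs at 829 TPM in replicate 1 and 177 in replicate 2.

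Most genes listed for lymphocytes and sympathetic neurons had few or no counts. The median was 0.0550 TPM in replicate 1 and 0.125 in replicate 2 for 8 T lymphocyte genes and 0.14 for 7 B lymphocyte genes, of which only Ighm (17.4 ± 1.65) reached 1 TPM. The sympathetic neuron genes Th, Dbh and Npy had no counts in either library, which allows each a share of up to 2.54e-05% of the expected counts of replicate 1 and 2.48e-05% of replicate 2. Schwann cell genes had a median of 1.18 TPM, with S100b (66.5 ± 4.26) and Mbp (6.68 ± 1.00) highest. Neutrophil genes had a median of 1.01 TPM. Hepatocyte genes had a median of 0.09 TPM in replicate 1 and 1.89 in replicate 2, keratinocyte genes 0.265 and 0.13, and the medians for mesothelial cells and for central neurons and astrocytes were 0. Y-linked genes such as Eif2s3y (24.0 ± 6.69 TPM) and Ddx3y (11.9 ± 3.03) were present and Xist had no counts, and the labels name the tissue as male.

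**Figure D2:**
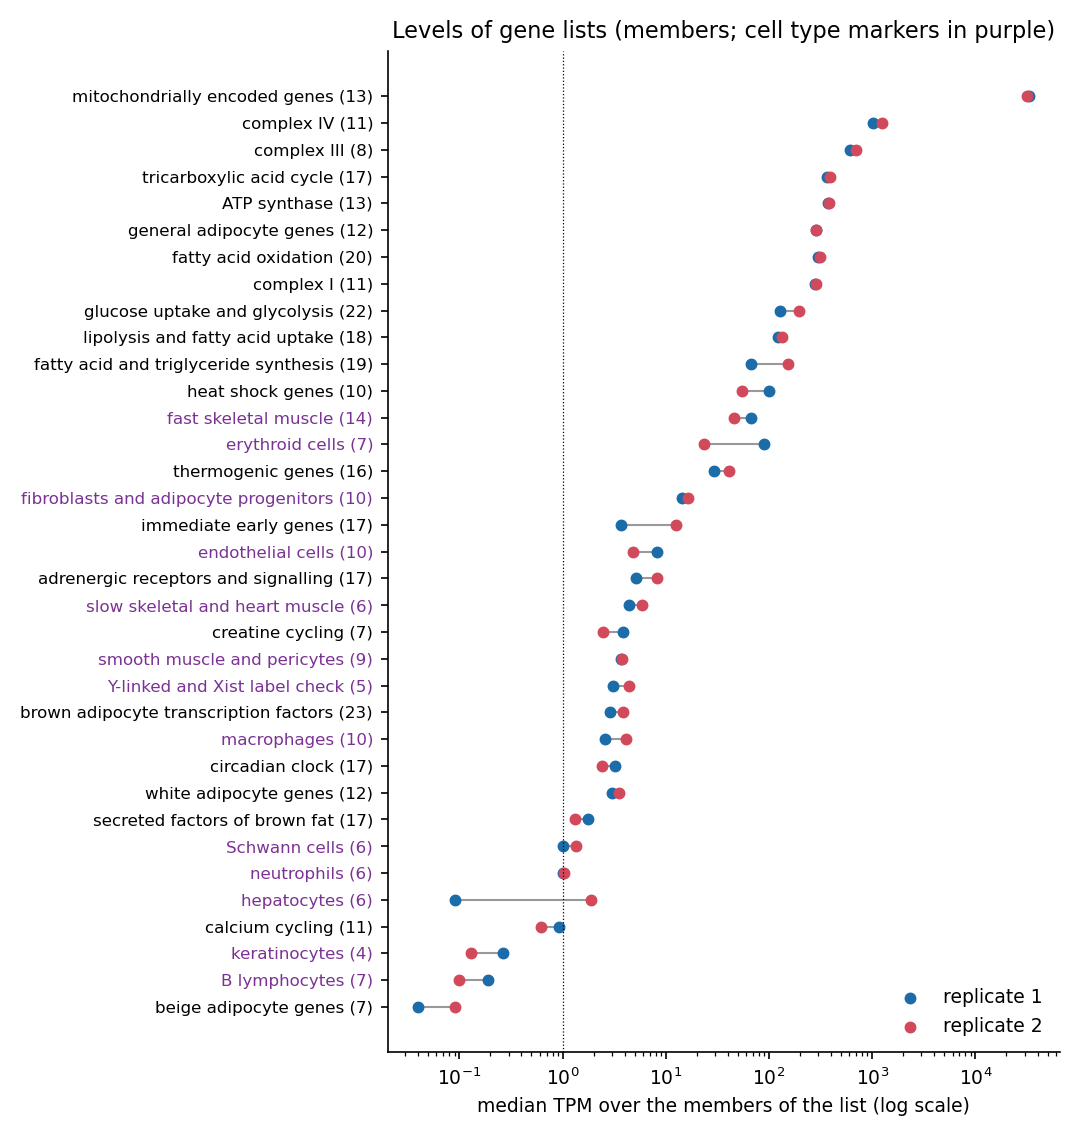
Median TPM over the members of each gene list (log axis) in replicate 1 (blue) and replicate 2 (red), with the number of members in brackets and cell type markers in purple. The nuclear lists of the respiratory chain lie between 277 TPM (complex I, replicate 1) and 1241 (complex IV, replicate 2) and thermogenic genes at 29.4 and 40.8; 4 lists without any member at 1 TPM in both libraries (T lymphocytes, sympathetic neurons, central neurons and mesothelial cells) are not drawn.

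Of 26 genes examined at transcript level, Ucp1, Cidea, Dio2 and Elovl3 have a single annotated transcript; of the other 22, 15 had the same leading transcript in both libraries. Lpin1, which makes diacylglycerol, had 87.7% ± 2.63 of its TPM in 1 transcript, Insr, the insulin receptor gene, 97.7% ± 3.27, and Adrb3 87.4% ± 2.83. Pparg had 55.2% ± 4.83 in its leading transcript and Gnas 56.1% ± 1.75. The leading transcript differed between the libraries for Ppargc1a, Pkm, Vegfa, Srebf1, Acaca, Camk2d and Hk2. That of Camk2d held 87.6% of the gene in replicate 1 and 25.8% in replicate 2, and that of Srebf1 held 43.4% and 8.82%. For Hk2 the leading transcript was a 594-base processed transcript, so the level of this hexokinase gene (87.7 ± 47.6 TPM) is uncertain.

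Across 10619 genes with a mean TPM of at least 1, log2(TPM + 1) of the 2 libraries correlated with Pearson's r 0.934 and Spearman's rho 0.898; genes are not independent replicates, so no p is attached. Against counting error alone, the chi-square of the counts was 70.9 per degree of freedom over 13753 degrees of freedom, a figure that also takes in any uncertain allocation of reads between genes. Genes with many counts weigh most in it, so it does not describe the typical gene. Over genes with a summed expected count of at least 100, the median absolute log2 difference was 0.246. Simulated Poisson counting error alone gave 0.0883. The biological coefficient of variation was 0.230 over 11618 genes. Of 8576 genes with a summed expected count of at least 100, 382 differed over 2-fold, 193 higher and 189 lower in replicate 2. Of these 8576 genes 8153 are nuclear protein-coding, and 245 of the 382 were among those, 116 higher and 129 lower. By the ratio of TPM the number was 572, with 446 higher and 126 lower, and the median of all tested protein-coding genes shifted to 0.21 on the log2 scale from 0.00.

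**Figure D3:**
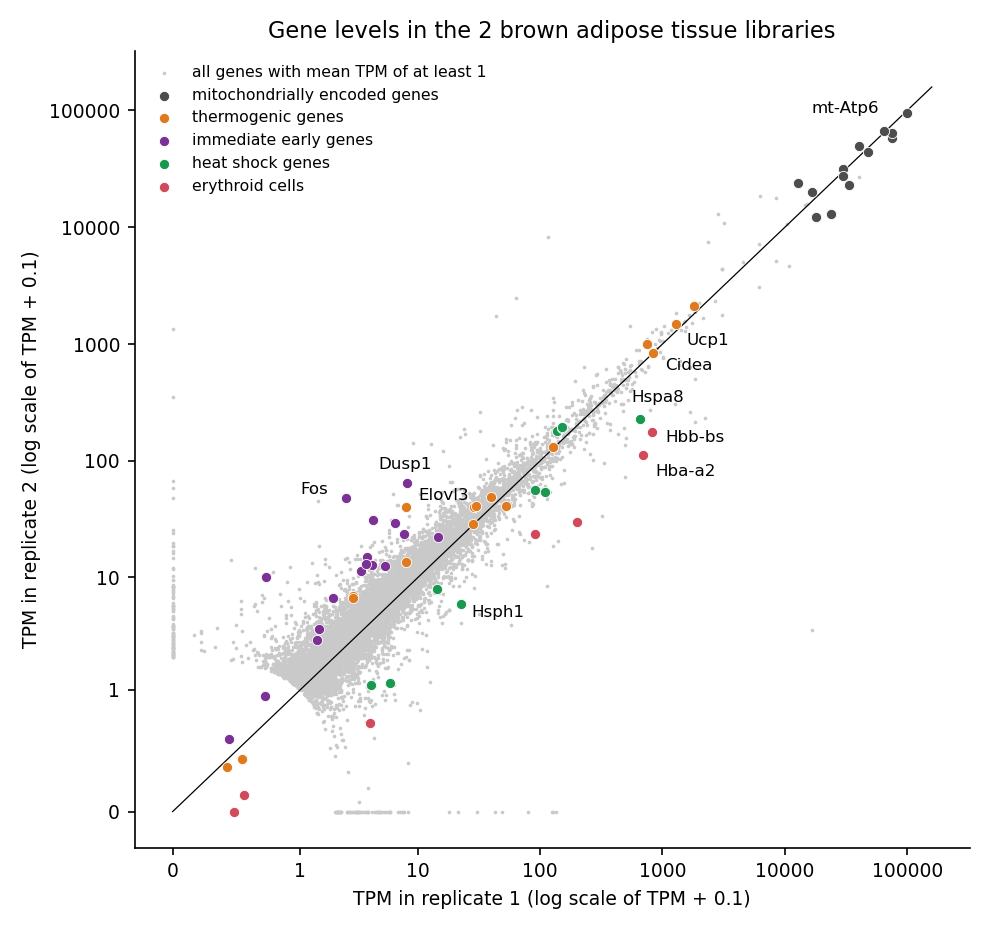
TPM of genes with a mean TPM of at least 1, in replicate 1 (horizontal) and replicate 2 (vertical), both on a log scale of TPM + 0.1, with 1 point per gene and all members of 5 gene lists in colour; the line marks equal levels. Fos lies at 2.5 and 47.98 TPM, above the line, and Hbb-bs at 829 and 177, below it.

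Immediate early genes, which cells switch on within minutes of a stimulus, had the highest median difference of the 29 lists tested. All 14 tested members were higher in replicate 2 and 12 of them by over 2-fold, with a median of 1.59 on the log2 scale. Fos (chromosome 12, 85473890 to 85477273, plus strand) had 56 expected counts in replicate 1 and 899 in replicate 2, a difference of 3.75. Dusp1, a phosphatase that dampens kinase signalling, differed by 2.80 (203 and 1581 counts), the nuclear receptor gene Nr4a1 by 2.68 (128 and 924) and Egr1 by 2.13 (265 and 1288), while Jun differed by 0.45. Sik1 (2.34) and Trib1 (1.74), a pair of kinase-related genes outside the list, were also among the 10 protein-coding genes furthest above replicate 1. The thermogenic list was higher in replicate 2 by a median of 0.25, with Elovl3 at 2.16, Dio2 at 1.12 and Ucp1 at 0.05. Macrophage genes were higher by 0.37, with 6 of 8 members above replicate 1. By TPM the medians were 0.37 for thermogenic and 0.49 for macrophage genes, or 0.15 and 0.28 relative to all genes, and both lay inside the range of random lists.

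Heat shock genes went the other way, with 9 of 10 members lower in replicate 2 and a median of -1.05 (-0.91 by TPM, where Hsp90aa1 and Hspd1 change sign). The chaperone genes Hsph1 (-2.35) and Hspa8 (-1.69, from 11891 to 4021 counts) were lower by more than 2-fold, as were Hspa1b, Hspa1a and Serpinh1, which were chosen for naming after their values were seen. Hspa1a and Hspa1b share most of their sequence, so the split between them is uncertain. Circadian clock genes had a median of -0.38, with 11 of 15 members lower in replicate 2. The 5 that passed 2-fold, also named after their values were seen, were the repressor genes Per2 (-2.75), Per3 (-1.38), Per1 (-1.15) and Cry1 (-1.02) and the regulator gene Nfil3 (-1.84), whereas Nr1d1 (0.22), Tef (-0.63), Rorc (-0.25) and Hlf (0.92) went both ways. Markers of other cell types differed beside these groups. All 5 tested erythroid genes were lower in replicate 2 (median -2.68), as were all 14 fast skeletal muscle genes (-0.76), 9 of 10 endothelial genes (-0.66) and 7 of 8 smooth muscle and pericyte genes (-0.29). The genes for alpha and beta globin, Hba-a2 (-2.76), Hbb-bt (-2.85), Hbb-bs (-2.38) and Hba-a1 (-1.73), share reads with their near-identical partners, and single values are uncertain. By TPM the medians were -0.10 for clock genes, -0.49 for fast skeletal muscle, -0.39 for endothelial genes and -0.15 for smooth muscle and pericyte genes. Relative to the shift of all genes by TPM they were -0.31, -0.70, -0.60 and -0.36.

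Lists of fat and energy metabolism had small median differences. Mitochondrially encoded genes had a median of -0.26, with 10 of 13 members lower in replicate 2, and of -0.12 by TPM. Glucose uptake and glycolysis had a median of -0.23, with 16 of 21 members lower. By TPM its median was 0.10, or -0.12 relative to the shift of all genes, and lay inside the range of random lists. The medians of fatty acid oxidation (-0.08), fatty acid and triglyceride synthesis (0.02), the tricarboxylic acid cycle (-0.09), general adipocyte genes (-0.03) and complex IV (0.02) lay inside the range of random lists matched on expression. Single genes of these lists still differed, such as Scd1 (1.55) and Cfd (-1.67), and so did Ppara (1.34), Lep (-1.15) and Adrb3 (-1.17) of other lists. Mitochondrially encoded genes passed the lower edge of the range of random lists by little (-0.2551 against -0.2546). So did smooth muscle and pericyte genes (-0.285 against -0.280). Random lists for mitochondrially encoded genes came mostly from nuclear genes at lower levels, so the matching on expression was poor there. In all, 11 of 29 lists with enough counted members lay outside the middle 95% of 10000 matched random lists. Members of a list may vary together between libraries, which random lists do not reproduce, so this range may be too narrow. By TPM, 10 lists did and 8 of the 11 were among them; the thermogenic, macrophage and glycolysis lists were not. With 1 library on each side these differences describe the 2 libraries, and no replicate check of them exists.

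**Figure D4:**
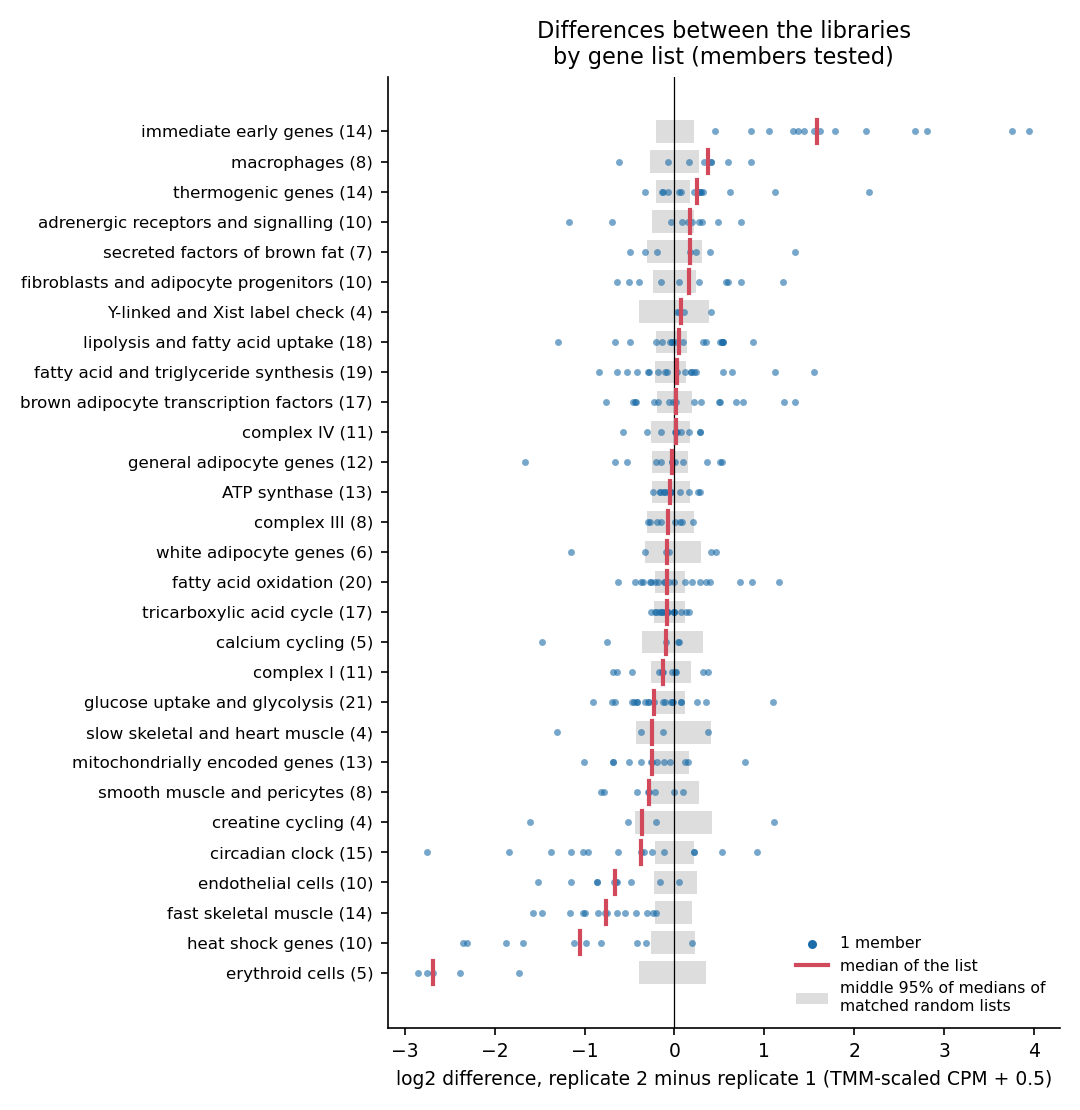
Difference in log2 CPM, replicate 2 minus replicate 1, for each gene list, with 1 blue point per member, the median in red and the middle 95% of medians of matched random lists in grey. Immediate early genes lie at a median of 1.59 and erythroid genes at -2.68, both far outside the grey bars. By TPM the glycolysis median changes sign to 0.10, but it is -0.12 relative to the shift of all genes.

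Among the 10 largest differences in each direction for protein-coding genes with at least 500 counts were globin, heat shock and immediate early genes and genes with close copies, but also others. Besides the genes already named, replicate 2 was lower for Dynll1 (-1.90), a dynein light chain gene, and for Bcl6 (-1.69), a transcriptional repressor. It was higher for Kxd1 (2.36), Rpl35 (1.92) and Gm20721 (2.43), which lies inside the span of Gnas on chromosome 2 (174330319 to 174346712). Gm11273 had 605 counts in replicate 1 and none in replicate 2, and Rpl10-ps3 differed by -2.17. For Gm11273, Rpl10-ps3, Rpl35 and Gm20721, at least 75.1% of 30-base windows occur in transcripts of other genes, so these counts are uncertain.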

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

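The tests of haemoglobin transcripts below were chosen only after the result was seen, and the comparison of transcript ends only after the overlap of intervals had been seen, though before its own result.

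Signal appeared on entries outside the annotated genes, above the limit that a count of 0 allows. The bacteriophage phiX, a control that sequencing runs carry, took 2.437% of expected counts in replicate 1 (exact 95% interval 2.43% to 2.45%) and 2.359% in replicate 2 (2.35% to 2.37%). The ERCC spike-in mix took 0.00106% in replicate 1 (0.000881% to 0.00126%) and 0.000565% in replicate 2 (0.000436% to 0.000713%), with 47 and 36 of its 96 sequences above 0. Entries with numeric identifiers took 0.005297% in replicate 1 (0.00489% to 0.00573%) and 0.005582% in replicate 2 (0.00517% to 0.00602%). The limit was 2.54e-05% in replicate 1 and 2.48e-05% in replicate 2. The ERCC share was lower in replicate 2 and the phiX share nearly equal, and the labels name a spike-in reference without saying which of these was added or how much. No explanation of these shares was tested.

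Immediate early genes had a median difference of 1.59 on the log2 scale between the libraries. Random lists matched on GC content or on transcript length never reached that median (percentile 100 under both), which argues against either as the cause. Cells that brought these transcripts would raise their own markers as well; of the 3 marker lists as abundant as Dusp1 in replicate 2 (64.2 TPM), the highest median was 0.16 for fibroblasts and adipocyte progenitors (SD of members 0.61, most abundant member 124 TPM), below the 0.79 set as the bound, with -0.76 for fast skeletal muscle (145 TPM) and -2.68 for erythroid cells (177 TPM). Markers of less abundant types were higher in replicate 2, among them macrophage genes (median 0.37, Lyz2 at 52.9 TPM) and the hepatocyte genes Alb (27 and 153 counts), Serpina1a (5.21 and 37.96), Apoa1 (0 and 20) and Ttr (0 and 26), and these types were not part of that test. Stimulation through adrenergic receptors and cyclic AMP stays open. Its targets Gadd45g (1.19), Crem (-0.26), Pde4b (-0.33) and Rgs2 (-0.68) were chosen before their values were looked at. Their median was -0.29, which met the bound set beforehand for counting against this explanation. They went both ways with an SD of 0.83, however, and the choice to leave such a spread open was made after the value was known. No other biological explanation was tested.

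Haemoglobin transcripts were lower in replicate 2. Reads moved between near-identical copies would leave the sums unchanged, yet the alpha genes summed differed by -2.61 and the beta genes summed by -2.47 (6.09-fold and 5.54-fold), which argues against such reads as the cause. Less red blood cell RNA in replicate 2 stays open: the alpha and beta sums differed alike, with a gap of 0.14, and Alas2, the haem synthesis gene of red cells, named after its value was seen, differed by -2.68 (98.6 and 11.6 counts), but these genes had prompted the question, and the red cell genes Slc4a1 and Gypa, with 10 and 2 counts summed, were too few to test it. Whole blood would bring neutrophils too, but their genes S100a8 and S100a9 summed to 39 and 46 counts, a difference of 0.11 (95% interval from counting error -0.50 to 0.73). The erythroid list holds 7 genes, shared with no other list, and no biological explanation beyond these blood cells was tested.

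Among 8153 tested nuclear protein-coding genes, 263 differed over 2-fold by TPM and not by counts, 253 of them higher in replicate 2; after the median shift of 0.21 between the scales was taken out, 126 did (84 higher, 42 lower). Another 169 differed by both and 76 by counts alone. Whether uncertain allocation of short reads among transcripts of different length is the cause stays open: the authors' intervals of the transcript whose share moved most overlapped between the libraries in 64.6% of the 263 genes (170), but also in 79.9% of 5891 other genes with several transcripts, so the overlap does not set these genes apart, a comparison weighed only after it was seen. Reads lying nearer the 3′ ends in replicate 2 would favour shorter transcripts at those ends, but the shorter transcript lay 3′ in 32.3% of 1618 genes where replicate 2 gained it and in 61.3% of 780 where replicate 1 did (difference -29.0 points, interval -33.1 to -24.8). The opposite, reads nearer the 3′ ends in replicate 1, was seen only in that test and is an untested hypothesis, and no biological explanation was tested.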

How the results depend on the processing

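Chosen only after the data were seen were the tests with the nuclear copies of mitochondrial genes, with protein-coding genes alone and with plain CPM for list differences.

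Counts of genes moved with the threshold by construction: 4607 genes were detected at a TPM of at least 5, and 810, 126 or 245 differed over 2-fold with a summed count of at least 20, of at least 500, or among protein-coding genes alone. The number was 379 with DESeq2 size factors, 385 with plain CPM and 424 with a pseudocount of 0.1. By TPM it was 572, but 446 of these were higher in replicate 2 and 126 lower, against 193 and 189 by counts. TPM shifted the median of all tested protein-coding genes to 0.21.

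By expected counts, the 10 most abundant nuclear protein-coding genes held 4.59% and mitochondrial genes 51.6%. Without the mitochondrial protein genes and rRNAs in the total the 10 genes held 5.56%. With all genes of the mitochondrial chromosome and the nuclear copies left out, the 10 genes held 7.73%, so this step is not from the copies alone. The mitochondrial protein genes alone held 55.0%, and 63.3% together with the rRNAs and the nuclear copies. All genes of the mitochondrial chromosome together with the copies held 69.4% ± 4.62 of TPM. Spike-ins held 0.436% of TPM. The units and totals themselves set these shifts. The correlation was 0.881 with a pseudocount of 0.1, 0.972 without a filter and 0.961 by posterior mean TPM; the coefficient of variation was 0.283 without a filter and 0.282 as the DESeq2 median. For these the cause was not tested.

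The ratio of Cox7a1 to Cox7a2 reversed to -0.32 and that of Slc27a2 to Slc27a1 to -0.11 by expected counts, which are not divided by length; of the other 28 ratios, 14 moved and 14 were the same within 1 SD. The glycolysis list reversed from -0.23 to 0.10 by TPM, which is -0.12 relative to all genes (percentile 17.2). By TPM, thermogenic genes (0.37, percentile 90.2) and macrophage genes (0.49, percentile 94.99) came inside the range of random lists; brown adipocyte transcription factors (0.57, percentile 99.8) and creatine cycling (-0.29, percentile 1.70) went outside it. The cause was not tested. The 11 lists outside the range were the same lists with DESeq2 size factors and plain CPM. Both only rescale whole libraries and shift lists and random lists nearly alike, so this sameness was built in and adds no support. The immediate early median was 1.59, 1.65, 1.62 and 1.67 under TMM, TPM, DESeq2 and plain CPM.

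The number of lists in the top 5% of levels was 21 of 39, and 21 to 22 with each library alone. This rank is against random lists from all protein-coding genes, most of which did not reach 1 TPM in both libraries. With 1 library the medians of the synthesis, creatine, immediate early, beige, endothelial, erythroid, T lymphocyte, keratinocyte and hepatocyte lists moved over 1.5 times. Families whose lead exceeded the difference between the libraries were 29, and 26 by counts. Isoform genes with a shared leading transcript were 19, the 4 with 1 transcript included, and 19 to 20 by counts, posterior mean TPM or protein-coding transcripts alone; 1 library alone cannot test this. Rescaling TPM without mitochondrial genes and spike-ins moved 36 of 39 list medians by construction. Depth limits genes below 2.54e-05% of counts, and with 2 libraries no spread within either side exists.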

Other observations

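No test was added for the values below. The genes Gm42418, Alb, Apoa1 and Ttr and the copies Gm29216, Gm10925, Gm28661, Gm28438, Gm28439, Gm10222 and Gm28437 were chosen for description after their values were seen.

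Some copies of mitochondrial sequence in the nuclear genome took very different counts in the libraries, and others nearly the same. The 7 annotated copies lie on chromosome 1 between 24611535 and 24616197, and at least 97.2% of the windows of each are also in the mitochondrial genome. Gm29216 had 94963 expected counts in replicate 1 and 19.5 in replicate 2, Gm10925 had 932 and 65646, and Gm28661 had 22855 and 104180. Gm28438 had 42060 and 18133. Gm28439 (158533 and 165152), Gm10222 (48282 and 50250) and Gm28437 (2260 and 1888) differed little. Together the copies held 3.21% and 3.43% of gene counts in replicates 1 and 2, so their sum differed far less than Gm29216, Gm10925 or Gm28661 did. Reads cannot be assigned between a copy and its mitochondrial source where the sequence is the same.

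Gm42418 (chromosome 17, 39846958 to 39848788, plus strand), annotated as a long noncoding RNA gene, held 1.21% of gene counts in replicate 1 and 3.47% in replicate 2. Its TPM was 6278 and 18597, and it differed by 1.43 on the log2 scale. Sequence that it may share with other RNAs was not checked, so whether these reads came from this gene is not known.

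Hepatocyte genes had few counts in either library and more in replicate 2. Alb had 27 and 153 expected counts in replicates 1 and 2, a difference of 2.16. Apoa1 had 0 and 20 and Ttr 0 and 26, where a count of 0 in replicate 1 allows a share of up to 2.54e-05% of expected counts.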
